A study of Mus musculus with 6 samples.

How the data were processed

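RNA from flash-frozen skeletal muscle of 6 mdx samples was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample, per the labels' protocols. The authors deposited 1 table with an intensity for each of 24922 probe sets on each array. Per the submitters' processing notes the values come from RMA in Affymetrix Power Tools, which corrects the background, normalizes the arrays to common quantiles and summarises probe sets; versions and any further step are not given in the sources used here. The deposited intensity values are on a linear scale, with medians near 150 and all values above 0, while the test had been planned for log2 values; log2 was therefore taken before any test, with no pseudocount, as the plan provided for. Quantile normalization by the authors removes differences between arrays in overall brightness, but the deposited lower quartiles still differ between arrays, from 51.2 to 57.7, so small differences among dim genes can come from the processing. RMA values of dim probe sets are also drawn together, which understates their differences.

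Probe sets were named through the platform's annotation table. Of 24922 rows, 21425 had 1 gene symbol, 1399 had several and were not used for genes, and 2098 were not listed there and stayed unnamed. Symbols were looked up by Entrez identifier in a mouse gene table (assembly GRCm38.p6, used for names only), where 21347 matched and 0 needed an update; the other 78 kept the symbol of the annotation. Where a gene had several probe sets, the one with the highest mean over the 6 arrays was used, which concerned 921 of the 19752 genes. Every gene named under the rule below had 1 probe set. No intensity filter was applied. Gbp2, Areg and Spp1 are not analysed here, because no probe set carried their symbol alone.

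Samples were grouped by the treatment in their titles. Each gene was tested on the log2 scale with limma (lmFit and eBayes, two-sided, version 3.58.1 in R 4.3.3) with group as the only term, and p-values were adjusted by Benjamini-Hochberg over all 19752 genes, with a threshold of 0.05. Intervals are limma's moderated 95% intervals. The 36 gene lists were fixed from textbook knowledge before the data were examined, with 630 of 694 entries measured (602 distinct genes), and were tested with camera at its preset correlation of 0.01, adjusted over the 36 lists. Camera with an estimated correlation, fry and a rank version of camera were run as alternatives. Camera compares a list with the other genes, whereas fry asks whether a list's genes move on balance one way and compares it with nothing. A list's mean per array is the average of its members' log2 values, each relative to its mean over the 6 arrays. Single values were compared by exact two-sided permutation of the arrays.

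The genes named in the text follow a rule written before the data were examined. It takes the 10 genes with the largest rise and the 10 with the largest fall past the threshold without overlap between groups, filled up, where fewer pass, by the smallest unadjusted p among genes with a log2 difference of at least 0.5 and no overlap; predicted genes, small RNA genes and receptor segments are skipped. No gene passed, so both sets were filled, with 10 higher and 7 lower genes. The rule adds the 4 members with the largest statistic of each list that passed and of the regulatory T cell list, and 32 fixed genes, 28 of them measured. Other genes are named as chosen after their values were seen, or because they passed adjusted over a list alone.

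The fit was tested on simulated data with the variances estimated from these arrays. In this gene test the genes were independent and the arrays shared no structure, unlike the real arrays, so recovery in the real data may differ. In the simulated comparison over 19752 genes with 200 changed genes, the fit recovered 37.0% of changes of 0.5 log2 units, 95.6% of changes of 1 and 100% of changes of 2. With 20 changed genes it recovered 1.43%, 77.9% and 100%. False calls averaged 8.20 per simulation with 200 changed genes and 0.65 with 20. For a list of 28 genes with no shift, camera with the preset correlation passed p 0.05 in 1% of 200 simulations when genes were independent and in 64% when they shared a correlation of 0.775, the value estimated for the macrophage list; with an estimated correlation that share was 2%. For 23 genes with a correlation of 0.432 and no shift, as in a list of glucocorticoid targets, the shares were 47.5% and 5.5%.

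Alternatives to each choice were a second quantile normalization, median centring, a variance trend with robust fitting, array weights, filters at the 30th and 50th percentile of mean intensity, the mean of all probe sets, all rows without naming, other thresholds, treat against a 1.2-fold change, the number in the titles as a replicate block, and leaving out each array in turn. Chosen after the data were examined were Xist level as a covariate, the 4 arrays with high Xist alone, the level of the lower quartile as a covariate, the genes without Xist and the Y-linked genes, complement without the genes shared with the macrophage list, and the 5 arrays without rat IgG 3 quantile normalized again. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The dose in the labels was left out because its unit is doubtful.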

Results

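Gene expression was measured in skeletal muscle of mdx mice, which lack dystrophin and whose fibres degenerate and regenerate amid immune cells. The question, from the study's title, was what depletion of regulatory T cells changes in dystrophic muscle. A group of 3 samples came from mice given anti-CD25, clone PC61, an antibody to the interleukin-2 receptor alpha chain that regulatory T cells carry in quantity. The other 3 samples came from mice given rat IgG as the control antibody. Both antibodies were injected 2 times, on days 17 and 20 of age. The design text puts dissection 7 days after the second dose, which is day 27, whereas the sample labels give an age of 6 weeks, which is day 42. Nothing in the labels states whether the 3 replicates of a group are separate animals, so p-values measure only the spread between these samples, which may be partly technical. Each sample was hybridised to 1 Affymetrix array, and the number of arrays limits the precision. The median intensity ran from 149.8 to 151.5 over the 6 arrays. Pearson correlations across genes, which are not independent replicates, were 0.991 to 0.996 within groups and 0.992 to 0.995 between groups, and 5 of the 6 arrays lay closest to an array of their own group. The exception, rat IgG 3, correlated at 0.991 with each array of its own group, below every correlation between groups. It lay closest to anti-CD25 2, at 0.995. The first principal component, the direction in which the arrays varied most, held 38.7% of the variance. It did not separate the groups (exact two-sided permutation p = 0.4).

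Xist, the RNA that coats the inactive X chromosome, and the Y-linked genes Kdm5d, Eif2s3y and Uty divided the arrays in a way that the labels, which call every animal male, do not state. On 4 arrays, rat IgG 1 and 2 and anti-CD25 1 and 2, Xist lay between 11.77 and 11.94 log2 units and the Y-linked genes lay at 5.09 or below. On the other 2 arrays, rat IgG 3 and anti-CD25 3, Xist lay at 5.48 and 5.49 and the Y-linked genes lay at 7.80 or above. Each treatment group held 2 arrays of the first kind and 1 of the second, so the samples of a group came from more than 1 animal. The arrays also differed in their dim range. The lower quartile of intensity was 57.6 on rat IgG 1, 57.7 on rat IgG 2 and 56.5 on anti-CD25 3, and 51.2 to 51.9 on the other 3 arrays. Immediate early and heat shock genes, which respond to handling, had a list mean of 0.55 log2 units on rat IgG 3 and -0.36 on rat IgG 1, relative to the mean over the 6 arrays.

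**Figure D1:**
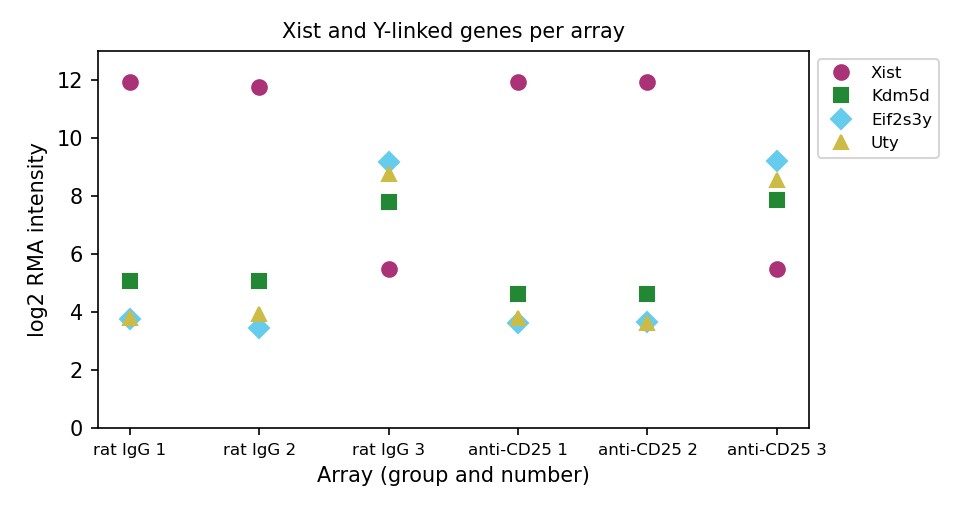
Log2 intensity of Xist and of the Y-linked genes Kdm5d, Eif2s3y and Uty, 1 point per gene and array. Xist lay at 11.77 or above on 4 arrays and at 5.49 or below on rat IgG 3 and anti-CD25 3, where the Y-linked genes were high.

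Foxp3 and Il2ra, transcripts that mark regulatory T cells, were dim and differed little between the groups. Foxp3, the transcription factor of the lineage, measured 6.57 ± 0.13 log2 units (SD, n = 3) with rat IgG and 6.48 ± 0.11 (SD, n = 3) with anti-CD25. Il2ra, which encodes the antibody's target, measured 5.67 ± 0.090 (SD, n = 3) and 5.66 ± 0.12 (SD, n = 3). These Il2ra means lay below the lower quartile of every array, 5.68 to 5.85 log2 units, and the Foxp3 means below every array's median. RMA understates differences of dim probe sets, so small values here do not show that these transcripts were unchanged. The difference, anti-CD25 minus rat IgG throughout, was -0.092 for Foxp3 (95% interval -0.32 to 0.13) and -0.0049 for Il2ra (95% interval -0.22 to 0.21). Foxp3 differed by -0.23 within the 4 arrays with high Xist and by 0.18 between the 2 others, Il2ra by 0.094 and -0.20, and the Foxp3 difference was -0.035 without rat IgG 2, -0.16 without rat IgG 3 and -0.16 without anti-CD25 3. The exact two-sided permutation p was 0.3 for Foxp3 and 0.9 for Il2ra, in a design of 3 against 3 whose smallest possible p is 0.1. The sign for Il2ra turned to 0.060 after a second quantile normalization. Of the 23 measured genes of the regulatory T cell list, 16 were lower and 7 higher with anti-CD25, with a mean difference of -0.048 (camera adjusted p = 0.667). The members with the largest statistics were Ctla4, an inhibitory receptor, at -0.21 (SE 0.079), Lrrc32, which presents latent TGF-beta, at -0.24 (SE 0.10), Ebi3 at 0.18 (SE 0.10) and Gpr83 at -0.17 (SE 0.10). Ctla4, at 5.45 with rat IgG, is among the 30% dimmest genes. Their median difference was -0.080 as deposited and -0.0033 after a second quantile normalization, so small falls there can come from the processing. Other list members were dim too, such as Il10 at 4.82 and Klrg1 at 5.06 with rat IgG. The median of the 23 list members, -0.078, lay close to the -0.080 of the dimmest genes, so the excess of lower members can come from the processing too. Over the alternatives the list mean ran from -0.089 to -0.0075. None of the 23 passed the test, adjusted over all genes or adjusted over the list alone.

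Across all genes, those named here have the smallest unadjusted p among genes with a difference of at least 0.5 and no overlap between groups. Timp4, an inhibitor of matrix metalloproteinases, was 2.04-fold higher, from 7.41 ± 0.17 (SD, n = 3) to 8.44 ± 0.27 (SD, n = 3), a difference of 1.03 (SE 0.14). Ms4a4a, a surface protein of macrophages, differed by 1.03 (SE 0.23) and its relative Ms4a6d by 0.70 (SE 0.17). Mertk, a receptor kinase through which macrophages engulf dying cells, differed by 0.71 (SE 0.16), and Cd163, the scavenger receptor for haemoglobin and haptoglobin, by 0.51 (SE 0.12). Il7r, the interleukin-7 receptor alpha chain, differed by 0.83 (SE 0.19). The other 4 genes taken by the naming rule in this direction were Ell2 at 0.59, Npy1r at 0.58, Emb at 0.62 and Pde3b at 0.62. Lower with anti-CD25 were Dusp10, a phosphatase of MAP kinases, at -0.61 (SE 0.097), the transcriptional repressor Bcl6b at -0.75 (SE 0.13), Tnfsf10, which encodes the death ligand TRAIL, at -0.54 (SE 0.10), and Nr1d1, a repressor of the circadian clock, at -0.58 (SE 0.12). Sec14l5, Plekhh3 and Kap, at -0.51 each, completed the 7 lower genes that met the rule. Kap and Npy1r are among the 30% dimmest genes, whose median difference was -0.080 as deposited. Kap differed by -0.72 within the 4 arrays with high Xist and by -0.094 between the 2 others. The rule takes only genes whose groups do not overlap, so the absence of overlap in these 17 genes is no result.

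None of the 19752 genes passed limma's test at an adjusted p of 0.05 or 0.1. The smallest adjusted p was 0.7496 and the smallest unadjusted p was 6.25e-05, for Timp4. At an unadjusted p under 0.05 there were 1240 genes, 454 higher and 786 lower with anti-CD25, where chance alone gives 987.6, and limma's treat against a 1.2-fold change also called 0. After a second quantile normalization the count was 628 higher and 675 lower. The 30% dimmest genes held 38 of the higher and 454 of the lower genes, and their median difference was -0.080, against -0.0033 after that normalization. Groups did not overlap in 2320 genes (11.7%), where chance gives 10%. The median 95% interval reached 0.22 log2 units to each side. Without rat IgG 3, 7 genes passed, all higher: Timp4, Ms4a4a, Ccr1, Has1, Mgat4a, Slc10a6 and Socs3. These were singled out after their values were seen, and 0 passed when the 5 remaining arrays were quantile normalized again.

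**Figure D2:**
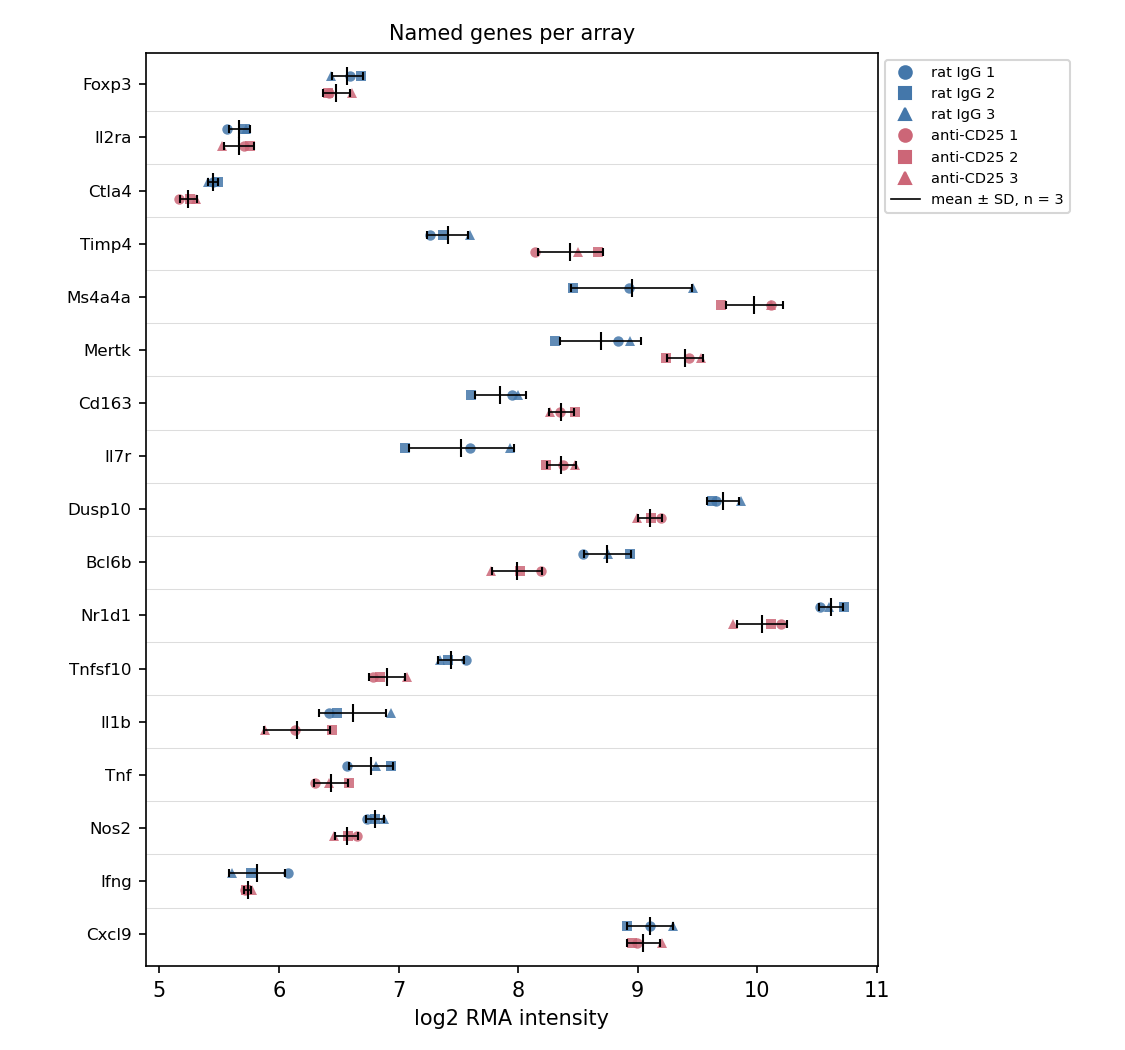
Log2 RMA intensity of 17 genes named in the text, 1 point per array, with the mean and SD of the 3 arrays of each group. Timp4, Ms4a4a, Mertk, Cd163 and Il7r lay higher on every anti-CD25 array than on every rat IgG array, as their selection required, and Foxp3 and Il2ra overlapped between the groups.

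Monocyte and macrophage genes were higher as a group on the anti-CD25 arrays. Of 28 measured genes, 26 were higher, with a mean difference of 0.33 and a median of 0.32. Beside Mertk, the strongest members were the tetraspanin Cd53 at 0.47 (SE 0.16), the IgG receptor Fcgr3 at 0.49 (SE 0.18) and the lysosomal protein Cd68 at 0.45 (SE 0.17). The list passed camera with its preset correlation (adjusted p = 1.07e-14), and this call was lost with adjusted p = 0.996 with an estimated correlation, whose value for this list was 0.775. The adjustment gave all 36 lists that same adjusted p, so it does not rank them. Unadjusted, camera with an estimated correlation gave p = 0.120 for the macrophage list. Among the members, 8 had an unadjusted p under 0.05, 0 passed adjusted over all genes and 0 passed adjusted over the list alone. The list mean per array was -0.062, -0.44 and 0.0021 on rat IgG 1, 2 and 3 and 0.39, -0.12 and 0.23 on anti-CD25 1, 2 and 3, so the groups overlapped, and the exact two-sided permutation p was 0.3. The difference was 0.39 within the 4 arrays with high Xist and 0.23 between the 2 others. It was 0.20 without rat IgG 2 and 0.22 without anti-CD25 1.

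Genes of mitosis and S phase were higher in 26 of 29 members, with a mean difference of 0.22 (camera adjusted p = 8.68e-10, and with an estimated correlation unadjusted p = 0.206 and adjusted p = 0.996). Its leading members were the kinesin Kif2c and the kinase Plk1, at 0.29 each, Ccna2 at 0.33 and the kinetochore motor Cenpe at 0.36. The mean difference was 0.081 without rat IgG 2 and 0.13 without anti-CD25 3. Complement genes were higher in 12 of 14 members, 3 of which, C1qa, C1qb and C1qc, are also in the macrophage list. Their mean difference was 0.12 (camera adjusted p = 0.00289, and with an estimated correlation unadjusted p = 0.0996 and adjusted p = 0.996). Cr1l, a membrane regulator of complement, stood at 0.26, the anaphylatoxin receptors C3ar1 and C5ar1 at 0.31 and 0.20, and C1qb at 0.20. The mean was 0.075 without rat IgG 2 and 0.11 without the 3 shared genes, the call was lost without anti-CD25 1 (0.094), and the difference was -0.0040 between the 2 arrays with low Xist. Genes of alternatively activated or resident macrophages were higher in 17 of 24 members, with a mean of 0.087 (camera adjusted p = 0.0185). With an estimated correlation, 0.028 for this list, camera gave unadjusted p = 0.0560 and adjusted p = 0.996. Cd163 passed adjusted over the list alone (adjusted p = 0.0473, limma), and Il4ra at 0.39, the scavenger receptor Stab1 at 0.33 and the lectin Clec10a at 0.30 did not. The call was lost without rat IgG 1 (0.048) and without anti-CD25 2 (0.050), the mean was 0.15 without rat IgG 3, and it was -0.079 between the 2 arrays with low Xist. No member of these 3 lists passed adjusted over all genes, and fry called 0 of the 36 lists (smallest adjusted p = 0.880).

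**Figure D3:**
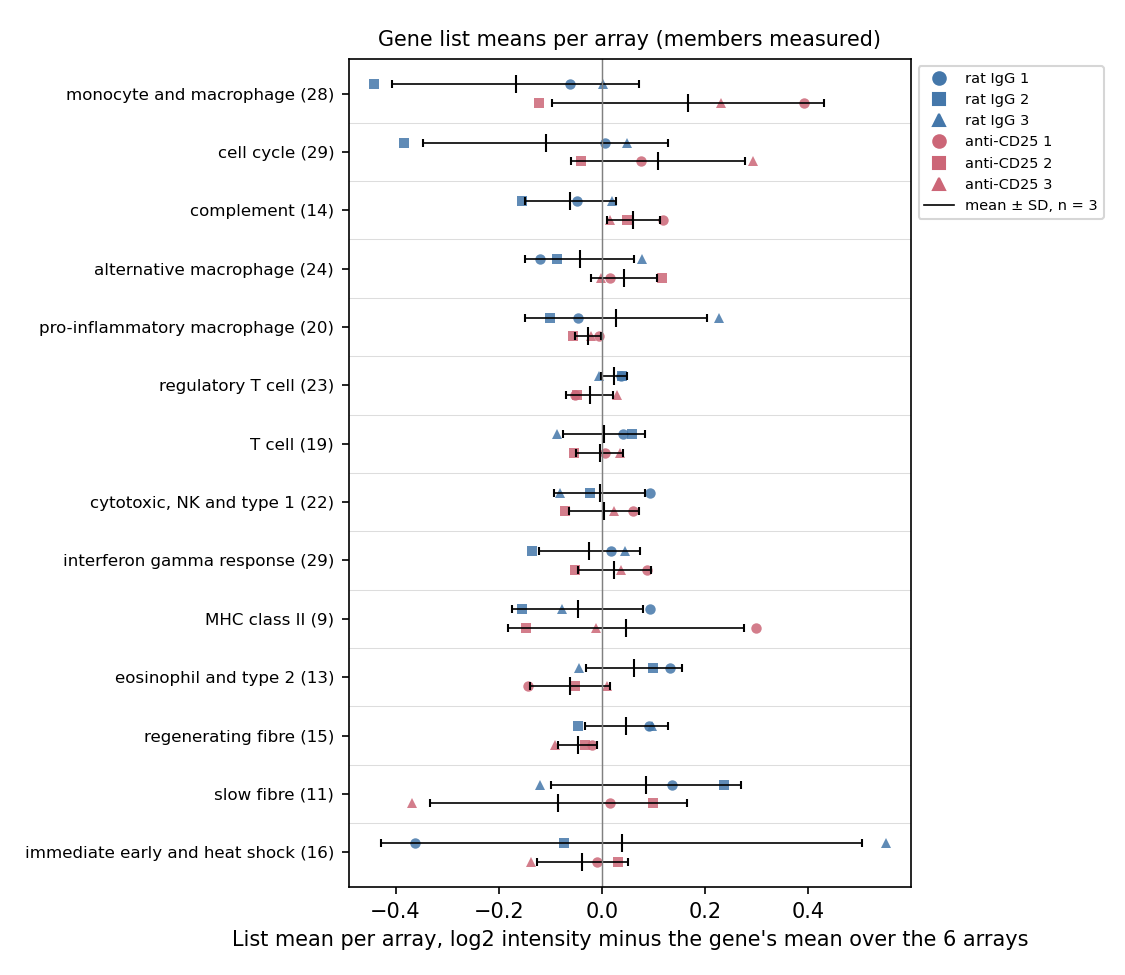
Mean of each gene list per array, in log2 units relative to each gene's mean over the 6 arrays, with the mean and SD of the 3 arrays of each group and the number of measured genes in brackets. The macrophage list ran from -0.44 on rat IgG 2 to 0.39 on anti-CD25 1, and the groups overlapped.

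Among products of classically activated macrophages, Il1b differed by -0.46 (SE 0.17), with -0.17 within the 4 arrays with high Xist and -1.05 between the 2 others, Tnf by -0.33 (SE 0.12) and Nos2, the inducible nitric oxide synthase, by -0.24 (SE 0.087), and none of the 3 passed the test. Their list had 12 of 20 members lower and a mean of -0.054, a direction that rested on rat IgG 3, where the list mean was 0.23, and turned to 0.046 without that array and to 0.042 within the 4 arrays with high Xist. Genes of the interferon gamma response, the signal of type 1 immunity, were higher in 15 of 29 members with a mean of 0.049, which turned to -0.0073 without rat IgG 2 and was called without rat IgG 3 (0.083) and without anti-CD25 2 (0.087). Ifng itself differed by -0.080, Cxcl9 by -0.056, Cxcl10 by 0.12, Ciita by 0.072 and Cd274 by -0.020. Within the 4 arrays with high Xist Ifng differed by -0.20 and Cxcl10 by 0.37, against 0.16 and -0.38 between the 2 others. Cxcl9, Ciita and Cd274 kept their sign in both. All calls in this paragraph with an array left out are at the preset correlation, and over all arrays each of these lists had adjusted p = 0.996 with an estimated correlation. The means of the type I interferon response, MHC class I and MHC class II lists were -0.014, 0.022 and 0.094, and each turned sign with 1 array left out, to 0.028 without rat IgG 1, -0.017 without anti-CD25 1 and -0.032 without anti-CD25 1. Only 13 of 19 members of the MHC class I list were measured. The chain genes H2-K1 and H2-D1 were not, so its mean says little of the class I chains themselves. The MHC class II mean was 0.19 without anti-CD25 2, and that list was called in 1 of 21 alternatives. H2-Aa, a class II chain, differed by 0.026, which turned below 0 after a second quantile normalization. Lymphocyte lists lay near 0, with -0.0085 for T cells, 0.0082 for cytotoxic, NK and type 1 cells and -0.067 for B and plasma cells. Many members were dim, such as Cd3d at 4.95 and Gzmb at 4.86 log2 units with rat IgG. Others, such as Thy1 at 9.11, were not. Differences of dim genes are understated, so means near 0 do not show that lymphocytes were unchanged. Cd3e differed by -0.033, Cd8a by -0.12 and Gzmb by 0.044. Within the 4 arrays with high Xist and between the 2 others, in this order, the T cell list differed by -0.073 and 0.12, Cd3e by -0.26 and 0.42 and Cd8a by -0.25 and 0.13. The B and plasma cell list differed by -0.15 and 0.10 in the same order. Il7r, a member of the T cell list, passed adjusted over the list alone (adjusted p = 0.0380, limma). Dendritic, neutrophil and mast cell genes had means of -0.0086, -0.019 and -0.019, and chemokines -0.012. The T cell, dendritic, neutrophil, mast cell and chemokine means turned above 0 after a second quantile normalization, and the chemokine mean was 0.091, and called, without rat IgG 3. Eosinophil and type 2 genes had the lowest mean among the immune lists, -0.12, with 10 of 13 members lower, but it was -0.012 among members above the 30th percentile of intensity, since the low members are dim. This list was called in 4 of 20 alternatives, among them without rat IgG 3 (-0.18) and without anti-CD25 3 (-0.16). Il5 passed adjusted over the list alone (adjusted p = 0.0467, limma). Arg1 differed by -0.20 (SE 0.43), which turned to 0.34 without rat IgG 3 and to 0.40 within the 4 arrays with high Xist, Mrc1 by 0.23 (SE 0.11) and Il10 by -0.078. Il10 was 0.084 within those 4 arrays and -0.40 between the 2 others.

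Muscle and matrix genes showed no list past the test. Genes of regenerating fibres had 11 of 15 members lower and a mean of -0.094, with the embryonic myosin Myh3 at -0.36 (SE 0.20) and the perinatal myosin Myh8 at -0.27 (SE 0.14), which were -0.13 and -0.11 without rat IgG 1. The list mean was -0.14 without rat IgG 2. Satellite cell and myogenic genes had 13 of 18 members lower and a mean of -0.072, with Pax7 at -0.14, Myod1 at -0.17 and Myog at 0.0073, which turned below 0 after a second quantile normalization. Myog differed by 0.25 within the 4 arrays with high Xist and by -0.49 between the 2 others. The list mean was -0.034 without rat IgG 1, and the list was called without rat IgG 2 (-0.11), without anti-CD25 1 (-0.13), after a second quantile normalization (-0.088) and above the 50th percentile of intensity (-0.074), each time at the preset correlation, against adjusted p = 0.996 with an estimated correlation over all arrays. Slow fibre genes had a mean of -0.17, with 10 of 11 members lower, and fast fibre genes -0.034. The slow fibre mean was -0.028 without anti-CD25 3 and -0.093 without rat IgG 2. The slow fibre list was called in 4 of 21 alternatives, among them without rat IgG 3 (-0.27) and without anti-CD25 2 (-0.26), at the preset correlation. Camera with an estimated correlation over all arrays gave it adjusted p = 0.996. Dmd, the gene mutated in these mice, differed by -0.046 and its homologue Utrn by -0.036. Atrophy and denervation genes averaged 0.075, fibro-adipogenic progenitor genes -0.047 and endothelial genes -0.051. Matrix genes had a mean of 0.065 and a median of -0.0053, with Col1a1 at -0.040 and Timp1 at -0.029. The mean ran from 0.023 without rat IgG 2 to 0.12 without rat IgG 3. Ccn2, picked after its values were seen, was the only member with an unadjusted p under 0.05 (limma). It did not pass adjusted over the list alone. Ccn2 differed by 0.88, with 1.32 within the 4 arrays with high Xist and -0.010 between the 2 others. Timp1 differed by 0.16 and -0.41 in the same order. Respiratory chain, fatty acid oxidation and glycolysis lists averaged -0.044, 0.036 and -0.0062, the last of which turned above 0 after median centring. The lists for other tissues averaged 0.062 for adipocytes, -0.14 for Schwann cells, -0.043 for tendon and cartilage, -0.14 for red blood cells and -0.035 for skin epithelium, which turned above 0 after a second quantile normalization. Only 5 of 11 members of the red blood cell list were measured, with no globin gene among them. With 1 array left out the Schwann cell mean ran from -0.27 without rat IgG 1 to -0.023 without rat IgG 2, the adipocyte mean from -0.015 without anti-CD25 2 to 0.18 without anti-CD25 3, and the tendon and cartilage mean from -0.16 without anti-CD25 2 to 0.065 without anti-CD25 3. The matrix, atrophy and denervation, respiratory chain and Schwann cell lists were each called in 2 of 21 alternatives. Adipocyte genes were called in 3 of 21 and regenerating fibre genes in 1 of 21. None of these lists passed with an estimated correlation over all arrays. Over all 36 lists, 18 means turned sign and 33 turned sign or moved over 1.5 times without at least 1 array. The circadian list averaged -0.038 and the immediate early and heat shock list -0.076, a value that rested on single arrays: without rat IgG 1 it was -0.28 and without rat IgG 3 it was 0.18, and camera at the preset correlation called the list in both cases, in opposite directions, against adjusted p = 0.996 with an estimated correlation over all arrays. Camera's adjusted p for the 32 lists that did not pass ran from 0.131 to 0.990, and where 4 lists passed with all arrays, 11 passed without rat IgG 3, 7 without rat IgG 2 and 7 without anti-CD25 3. Median and mean had opposite signs for the fatty acid oxidation and the cytotoxic lists too, and camera's direction was up against a mean below 0 for the type I interferon, glycolysis and mast cell lists. Over all 36 lists 0 members passed adjusted over all genes and 6 passed adjusted over the list alone, Cd163, Il7r, Il5, Nr1d1, Ppargc1a and Klf1, a count that was 3 after a second quantile normalization, 42 without rat IgG 3 and 21 without anti-CD25 2.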

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

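Tests chosen only after the results were seen were those with Xist level or the lower quartile as a covariate, those on the 4 arrays with high Xist, those without Xist and the Y-linked genes, complement without shared genes, and 5 arrays quantile normalized again. The count of 0 genes was the same in 21 of 23 alternatives. It was 4 at an unadjusted p under 0.05 with a log2 difference of at least 1, and 0 to 7 with 1 array left out (7 without rat IgG 3). The 4 called lists kept their direction in every alternative run over at least 4 arrays, though 2 of them were below 0 between the 2 arrays with low Xist. Their number was 0 with an estimated correlation, 0 with fry, 9 on the 4 arrays with high Xist, and 4 to 11 with 1 array left out (7 without rat IgG 2, 11 without rat IgG 3, 7 without anti-CD25 3). The estimated correlation and fry ended the calls for macrophage (mean 0.334), cell cycle (0.218), complement (0.122) and alternative macrophage genes (0.0867) and leave the means as they are by construction; the estimated correlation changes the error, and fry also changes the question asked. The alternative macrophage call was also lost on ranks (0.0867), after quantile normalization (0.0893), above the 30th percentile (0.0843), with the lower quartile as a covariate (0.0453), and in part of its range with 1 array left out (0.0482 to 0.147). Complement lost its call with the lower quartile as a covariate (0.0906) and without anti-CD25 1, within 0.0753 to 0.163. Of the lists not called with all arrays, 2 turned from negative to called above 0 without rat IgG 3, chemokines at 0.0909 (range -0.0818 to 0.0909) and immediate early genes at 0.180 (range -0.276 to 0.180), the latter also on the 4 arrays with high Xist (0.230) and called below 0 without rat IgG 1 and with the lower quartile as a covariate (-0.229). For the other changes the cause was not tested. Unadjusted calls, 454 higher and 786 lower, became 844 and 1410 with array weights, 1143 and 1887 without rat IgG 3, 186 and 477 without rat IgG 2, 284 and 457 without anti-CD25 1, and 1081 and 3000 on the 4 arrays with high Xist; lower calls were 400 and 306 above the 30th and 50th percentile. Members passing adjusted over the list alone, 6 in all, ranged from 3 after quantile normalization to 42 without rat IgG 3. Arrays of the same number in the titles shared their Xist level, and deviations of same-numbered arrays correlated at 0.030, -0.0067 and -0.17. With them as a replicate block 0 genes and 5 lists passed, and 24 members passed adjusted over the list alone. Signal over background was not used here, so how far dim genes are limited is seen only in their median difference.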

Other observations

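Tests chosen only after the result was seen were those of the low rat IgG array, of sex, of the clock genes, of the split count for genes, the simulation for the glucocorticoid list, and all with Xist level or the lower quartile. Of the fatty acid oxidation list, in which 10 of 22 members were higher with anti-CD25, Ppargc1a, a coactivator of mitochondrial biogenesis, differed by 0.48 (SE 0.10) and passed adjusted over its list alone (adjusted p = 0.0292, limma). Of the others, the nuclear receptor Ppara stood at 0.32 (SE 0.10) and the mitochondrial carrier Ucp3 at 0.47 (SE 0.17). The factors Foxo1 and Foxo3 stood at 0.37 (SE 0.11) and 0.22 (SE 0.086), while Fbxo32, a ubiquitin ligase of muscle atrophy, stood at -0.35 (SE 0.15). Among type 2 genes, the lowest members were Il5 at -0.46 (SE 0.12), the eosinophil peroxidase Epx at -0.42 (SE 0.13) and Gata3 at -0.26 (SE 0.086), all among the 30% dimmest genes, whose median difference was -0.080 as deposited, and the list mean was -0.0117 above that percentile. The erythroid factor Klf1, also among the 30% dimmest genes, stood at -0.31 (SE 0.091). Apart from the lists' own members past their list alone, these genes were chosen after their values were seen, and none passed adjusted over all genes.

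Only 4 genes differed by at least 2-fold with an unadjusted p under 0.05. Beside Timp4 and Ms4a4a they were Gpnmb, a glycoprotein of lipid-laden macrophages, at 1.03 (SE 0.33), and Fkbp5, a target of the glucocorticoid receptor, at 1.01 (SE 0.28). In the clock list, Nr1d1 passed adjusted over the list alone (adjusted p = 0.0119, limma), and Arntl, which Nr1d1 represses, was also lower at -0.39 (SE 0.12), as was Cry2 at -0.21 (SE 0.083). Genes of the opposite arms of the clock had medians of -0.038 over 4 genes and 0.032 over 10 genes, a difference of -0.0695, with members on both sides of 0 in each, which decides nothing about the hour of dissection. On rat IgG 3, Socs3 stood at 9.77, against a mean of 8.05 on the other rat IgG arrays and 9.27 with anti-CD25, and Has1 at 8.35 against 6.89 and 7.85.

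The macrophage genes were higher with anti-CD25 by 0.334 on average. Differences between the arrays' intensity distributions are argued against as the whole cause, since the shift was 0.312 after a second quantile normalization that moved the dim genes, and 0.308 with the lower quartile as a covariate. Unequal sex is argued against, since each group held 2 arrays with high Xist and 1 without, and the lower of the shifts in these strata was 0.230. A single low array stays open, since the shift was 0.197 without rat IgG 2, and 10 splits of the 6 arrays are too few for a share under 0.05, with 3 of them, the real one included, at least as large as the real one (real 0.334, highest other 0.417). A larger share of macrophages in these muscles was not tested apart from a difference between individual samples.

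The same 10 splits are too few for the other counts. For genes they test nothing, since the real count is 0 and all 10 reach it by construction (highest other 0). Counting the real one, 8 gave as many lists (real 4, highest other 16). The split that follows the lower quartile, with rat IgG 1, rat IgG 2 and anti-CD25 3 on one side, called 8 lists and 3839 genes at an unadjusted p under 0.05, against 1240 for the real split, and 2120 after a second quantile normalization, which points to a structure of the arrays other than treatment. With the lower quartile as a covariate the real comparison gave 0 genes and 3 lists.

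The second pattern is the division of the arrays by Xist. RNA of both sexes mixed in each tube is argued against, since the Y-linked genes differed by -4.88 log2 units in the median between the 4 arrays with high Xist and the 2 others. All 4 genes, Xist and the 3 Y-linked genes, split the arrays alike. With Xist at 11.77 or above and the Y-linked genes at 5.09 or below, male RNA on the 4 arrays with high Xist is argued against. Female animals under a male label are a candidate explanation for these 4 of the 6 samples. Whether arrays were exchanged between the treatment groups cannot be told apart by this, since the groups differed by 0 in their number of such arrays. No biological explanation was tested.

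The third point concerns Il1b and Tnf at -0.46 and -0.33 and Cd163 and Mertk at 0.51 and 0.71, which were picked after their values were seen and did not pass adjusted over all genes, and for which a stronger glucocorticoid signal is a candidate explanation, tested on 23 target genes chosen after those 4 genes were seen. Their median difference was 0.240, with 18 of 23 higher and camera p = 4.98e-07 at the preset correlation, which met what had been written down before that test. The requirement was made stricter once this value was known, and under the stricter requirement the question stays open: p was 0.162 with an estimated correlation, and another split of the arrays gave a mean shift of 0.341 against 0.256. In simulations without a shift, run later at this list's size and correlation (0.432), camera at the preset correlation passed in 47.5%, and in 5.5% with an estimated correlation. The mean shift was 0.0879 without rat IgG 1, and Fbxo32, Klf15 and Trim63, which glucocorticoids induce in muscle, were at -0.35, -0.18 and -0.072.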
